A study of Drosophila melanogaster with 29 samples.

How the data were processed

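Gene expression was measured in Drosophila melanogaster embryos on 18 two-colour arrays and in adult flies on 11 single-channel arrays. Each embryo array set the RNA of mnn++ embryos, which overexpress Mnn1 from a GAL4-driven construct, against a control that carries the driver without the construct, per the labels. The labels name 2 such controls, cntrl1 and cntrl2, without saying how they differ. Embryos were collected over 2-4, 4-6, 6-8 and 2-16 h at 25 C, and each pairing was hybridised in both dye orientations. That gives 16 arrays of mnn++ against a control, and 2 further arrays set the controls against each other at 2-16 h. The adult arrays held flies of 3 to 5 days after eclosion: 6 female and 5 male arrays of wild type (wt), an X113_X84 control stock, heterozygotes and mnn- flies, which carry 2 mutant alleles of Mnn1 per their titles. The free-text description attached to the adult arrays calls all 11 homozygous null, which contradicts their titles, and the titles were used.

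The deposited embryo values are log ratios of the RNAs on an array, made with limma 2.12.0 per the submitters' processing notes, and no header states their log base or sign. They were read as log2 ratios, the limma convention. Each deposited array was centred near 0, with medians from -0.011 to 0.015 and SDs from 0.165 to 0.304. Swapped arrays had already been turned when the ratios were deposited: spot 12320 lay between -3.375 and -1.653 on all 10 arrays holding cntrl2, in both dye orientations, and between -0.201 and 0.272 on arrays of mnn++ against cntrl1. With that reading the difference between the controls worked out from mnn++ arrays and the one on the direct arrays had r = 0.30 across spots, against 0.0931 without it. Spots are not independent replicates. The sign of the ratios was then turned so that a positive value means more signal in mnn++. This direction is likely but not stated in any label: it rests on the overexpressed Mnn1 being higher in mnn++ in both dye orientations at 2-16 h. Signs from the embryo arrays all hold under that reading. Dye bias remained (median r 0.331 between arrays of the same orientation and -0.248 between opposite ones) and cancels when the orientations are averaged.

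The deposited adult values are log2 intensities per probe set summarised with RMA in affy 2.12.0, per the submitters' processing notes, with array medians from 5.464 to 5.533. Whether all arrays were summarised together is not stated. Arrays give no count of molecules, so their number limits the precision.

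Of 31464 spots in the embryo table, 1008 were empty on all arrays and 79 were missing on 1 array, which left 30377 tested. Of 14010 adult probe sets, 44 AFFX controls were left out and 13966 were tested. Among the 30456 spots with a value, 25174 name a single gene, 146 several genes and 5136 none. Of the probe sets, 12443 name a single gene, 327 several and 1196 none. Names were matched to current fly genes of the Release 6 assembly for 24214 spots and 12394 probe sets. Because the files name no assembly, no coordinates are given.

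The design was fixed before the data were examined. The dye orientations were averaged first. Averaging over the controls then gave 1 value per window, so mnn++ over 4 windows rests on n = 4, since the labels do not say whether the arrays of a window used separate RNA. The effect in each window came from the 8 dye-averaged comparisons in a single fit, and an F test compared 2-4, 4-6 and 6-8 h. The only spread in that fit is the difference between the 2 controls of a window. Where mnn++ RNA was shared between arrays, its own spread is left out of these SEs and p-values. Adult comparisons used all 11 arrays with sex as a term, or with a level per sex and genotype. Wt and control flies were pooled as non-mutant, and heterozygotes were a level of their own. Tests were two-sided, except the one-sided Fisher's exact test of the neighbours of Mnn1. Gene-level tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and Benjamini-Hochberg adjusted p under 0.05. The standard errors are those of the moderated fits unless given as SD.

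Genes named in the text follow a rule fixed before the data were examined: Mnn1 always, and, for mnn++ over 4 windows, mnn- against non-mutant adults and male against female, the 12 highest and 12 lowest changes past the threshold that name a single gene and go the same way in every replicate. Other comparisons give 6 per direction, and where fewer than 5 pass, the 10 smallest p-values are named as not passed. White (w), the usual marker of transgenes, was to be named too but neither array names it. From each list 2 to 4 members could be named. Other genes are said to have been chosen after their values were seen.

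The 24 gene lists were also fixed in advance. They cover heat shock and stress proteins, Hox genes, trithorax and Polycomb group, DNA damage repair and checkpoint, AP-1, JNK and TGF-beta signalling, cell cycle and DNA replication, segmentation, dorsoventral patterning and mesoderm, maternally loaded transcripts, early zygotic cellularization, muscle, neural, haemocyte and extracellular matrix, cuticle, antimicrobial response, detoxification, yolk and chorion, accessory gland, testis, dosage compensation and sex determination, circadian clock, digestive enzymes, fat body, and vision. Each list with at least 5 measured genes was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists tested in each comparison. Hox genes were measured for too few members and were not tested. A gene's value was the mean over its spots in embryos and its brightest probe set in adults.

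The scripts were tested on simulated data in which 200 genes were changed. The noise was normal, independent for every value, and had the moderated variance of each spot or probe set. No shared RNA, correlation between spots or lasting difference between controls was simulated. Recovery from the real data can therefore be lower than the shares given here. For mnn++ over 4 windows (30377 spots) 98% of changes of 0.25 on the log2 scale were recovered. For a window 14% of that size and 88% of changes of 0.5 were recovered. For mnn- against non-mutant adults (13966 probe sets) 82% of changes of 0.5 and 100% of changes of 1 were recovered, and in males alone 32% and 98%. False calls were 9.1%, 7.4%, 4% and 4.2% of the calls in these 4 simulations. Alternatives were other scalings, variance priors, definitions of a replicate, filters, control groups and each replicate left out in turn. A further 4 alternatives were added after seeing the data: requiring a difference from both controls, leaving out the wt male array and the X113_Y79 heterozygote array, pairing males with females of the same stock or allele pair, and leaving out the control arrays. Leaving out wt or control arrays in the tests of lists was added then too.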

Results

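The study profiled gain and loss of menin, the Drosophila homologue of the protein encoded by the human MEN1 tumour suppressor gene. Embryos overexpressing Mnn1 (mnn++) were set against 2 controls, cntrl1 and cntrl2, in 4 collection windows on 16 two-colour arrays, and the controls against each other on 2 arrays. Adults were profiled on 11 arrays: females of wt (1 array), control (1), heterozygotes (2) and mnn- (2), and males of wt (1), control (1) and mnn- (3). Among mnn- flies male 11 was Y79_Y79, and the others were X46_Y79 or Y79_X46 per their titles. Embryo values are log2 ratios turned so that positive means higher in mnn++, a direction that is likely but not stated in the labels. Adult values are log2 RMA intensities.

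The first question is whether the construct raised its own gene. In mnn++ embryos Mnn1 read higher than control at 2-16 h, by 0.62 ± 0.08 (log2, SE, 2 controls) on spot 12724 and 0.56 ± 0.09 on spot 12064. It was above 0 on all 4 arrays of that window for both spots. At 2-4 h the values were 0.14 ± 0.08 and 0.03 ± 0.09, at 4-6 h 0.15 ± 0.08 and 0.08 ± 0.09, and at 6-8 h 0.25 ± 0.08 and 0.24 ± 0.09. None of these passed: the adjusted p at 2-16 h was 0.565 and 1.00, and over 4 windows (0.29 ± 0.07 and 0.23 ± 0.07, n = 4) it was 0.106 and 0.227 by limma. Both passed in 1 of 6 alternatives at 2-16 h, with each array as its own value, and their adjusted p ran from 7.51e-04 to 1.00 and from 0.0067 to 1.00 over those alternatives. Over 4 windows neither passed in any of 11. The SEs in single windows come from differences between the 2 controls, so they may leave out the spread of the mnn++ RNA itself. Since the direction of the ratios was itself read from Mnn1 at 2-16 h, its sign there is no independent check of the labels.

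**Figure D1:**
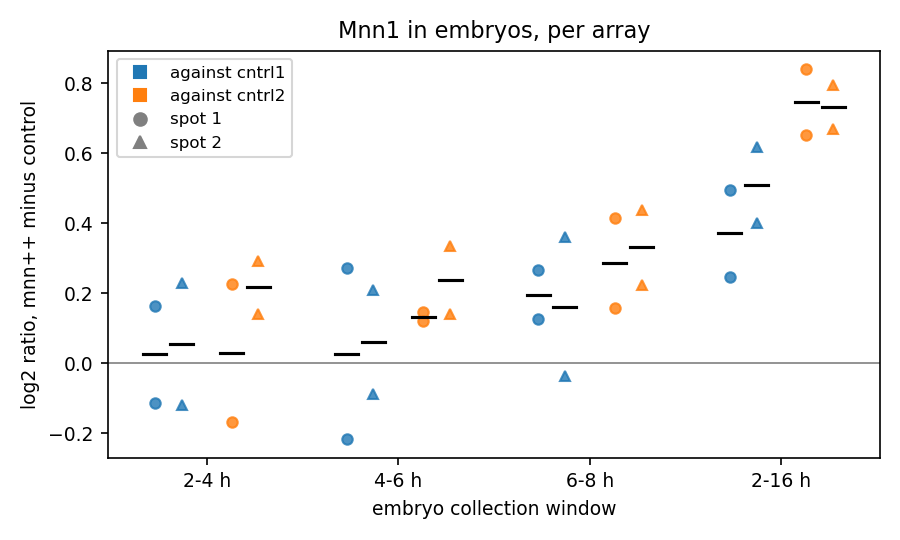
Log2 ratio of mnn++ to control for the 2 Mnn1 spots on each of the 16 arrays, by collection window (x axis) and control (colour), with black bars at the mean of each dye-swapped pair. Single arrays lie between 0.25 and 0.84 at 2-16 h and between -0.22 and 0.44 in the narrower windows.

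Which spots differed between mnn++ and control embryos over all windows was asked next. Over 4 windows 67 spots rose and 12 fell in mnn++ embryos out of 30377 tested, from 34 and 7 named genes, with limma and adjusted p under 0.05. At an unadjusted p under 0.05 there were 3475 spots, against 1519 by chance. The same kind of fit for cntrl1 against cntrl2 gave 2330, and spots of a gene are not independent. Among the risen genes were LysE, a lysozyme (0.37 ± 0.06, SE, n = 4 windows), AANATL4, a relative of arylalkylamine N-acetyltransferases (0.46 ± 0.05), Dronc, the initiator caspase (0.35 ± 0.04), and Prx3, a mitochondrial peroxiredoxin (0.33 ± 0.05). Those that fell included Tl, the Toll receptor (-0.38 ± 0.06), Nap1, a nucleosome assembly protein (-0.28 ± 0.05), kek1, an inhibitor of the EGF receptor (-0.25 ± 0.04), Snx16, a sorting nexin (-0.28 ± 0.04), and Ac76E, an adenylyl cyclase (-0.22 ± 0.04). The other risen genes taken by the naming rule were CG11164 (0.56), rtet (0.42), GILT3 (0.39), Syn2 (0.38), CG14683 (0.37), CG15098 (0.37), the esterase alpha-Est5 (0.36) and CG10102 (0.33), and the other fallen ones CG5568 (-0.41) and CG11700 (-0.23). Adjusted p of these 19 genes ran from 0.00456 for AANATL4 to 0.0356 for GILT3, and each went the same way in all 4 windows. Over the 11 alternatives of each gene the adjusted p reached as high as 1.00.

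Most of these changes were larger against cntrl2 than against cntrl1. The median absolute log2 ratio of the 79 called spots was 0.464 against cntrl2 and 0.0904 against cntrl1, where all spots had 0.0526 and 0.0374. AANATL4 (0.59 ± 0.12 against cntrl1, 0.34 ± 0.09 against cntrl2), Snx16 (-0.36 ± 0.04 and -0.20 ± 0.07), Ac76E (-0.22 ± 0.05 and -0.22 ± 0.05), kek1 (-0.20 ± 0.05 and -0.30 ± 0.06) and LysE (0.35 ± 0.08 and 0.40 ± 0.07) went the same way against either in the mean of 4 windows. In single windows AANATL4 was at -0.03 against cntrl1 at 4-6 h, and Snx16 at 0.08 against cntrl2 at 2-16 h. Of the 79 called spots 22 had the same sign in all 8 comparisons of a window and control. CG11164 (0.08 ± 0.05 and 1.04 ± 0.13) and Dronc (0.11 ± 0.04 and 0.60 ± 0.06) were above 0 against both but larger against cntrl2, and CG5568 was lower against cntrl2 only (0.00 ± 0.05 and -0.81 ± 0.09). Spots 12320 and 12980, called but without a single gene name, were chosen after their values were seen. Against cntrl1 both were at -0.04 ± 0.04, and against cntrl2 they were at 2.39 ± 0.18 and 2.05 ± 0.14. Against cntrl1 alone limma called 0 spots, with 2100 at an unadjusted p under 0.05, and against cntrl2 alone it called 49 higher and 6 lower. The count of 79 became 2 without the 6-8 h window, 15 without 2-4 h, 18 without 4-6 h and 145 without 2-16 h, and 0 with each array as its own value. The highest of these counts came without 2-16 h, the window where Mnn1 itself read highest, so the calls do not rest on that window.

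**Figure D2:**
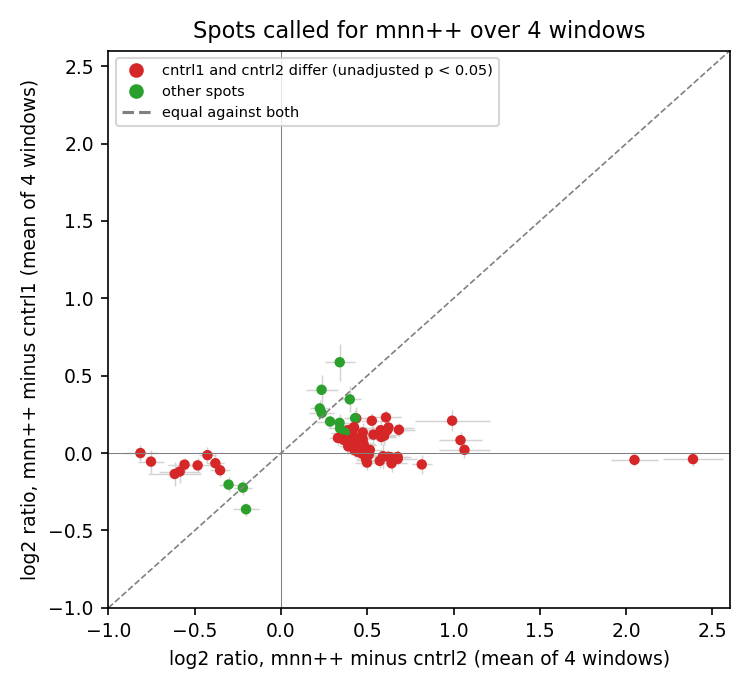
The 79 spots called for mnn++ over 4 windows, with the log2 ratio against cntrl2 (x axis) and against cntrl1 (y axis), means of 4 windows with bars of 1 SE. Red points differ between the controls at an unadjusted p under 0.05 (66 of 79 spots), green points do not, and the dashed line marks equal ratios against both.

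Of the lists, segmentation genes and early zygotic cellularization genes tested lower in mnn++ over 4 windows. For segmentation 11 of 17 measured members were below 0 and 0 passed alone (adjusted p = 0.0324 by camera, and adjusted p = 0.845 with an estimated correlation). The lowest were the gap gene Kr at -0.14 ± 0.04, the segment polarity gene en at -0.13 ± 0.04 and the pair-rule gene opa at -0.10 ± 0.03. Of the early zygotic genes 7 of 8 were below 0 (adjusted p = 0.0492, and adjusted p = 0.845 with an estimated correlation). There halo (-0.18 ± 0.04) was past the threshold adjusted over the list alone, and 0 members over all spots. Against cntrl1 alone segmentation genes had adjusted p = 0.971 and early zygotic genes 0.0457, and against cntrl2 alone 0.00178 and 0.0725. These were 0.982 and 0.627 with an estimated correlation against cntrl1 and 0.762 for both lists against cntrl2.

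The other 21 lists did not pass over 4 windows. Menin acts in histone methylation complexes of the trithorax group, and trithorax and Polycomb genes (7 of 17 above 0, adjusted p = 0.834), heat shock proteins (2 of 11, 0.174), AP-1, JNK and TGF-beta signalling (5 of 15, 0.657), DNA damage repair (10 of 27, 0.807) and cell cycle genes (9 of 21, 0.793) were among them. Maternally loaded transcripts were above 0 for 12 of 18 (0.657) although Tl fell, and testis genes for 8 of 15 (0.834) with tomboy20 risen (0.20 ± 0.03). The remaining adjusted p were 0.298 for detoxification and clock genes, 0.307 for dorsoventral genes, 0.481 for cuticle, 0.657 for fat body, 0.682 for sex determination, 0.722 for antimicrobial and 0.784 for haemocyte genes. They were 0.834 for accessory gland and for yolk and chorion genes, 0.846 for vision, and 0.895 for muscle, neural and digestive genes. Vision and digestive genes had a median and a mean of opposite sign.

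Whether the effect depended on embryo age was asked window by window. At 2-4 h the early zygotic genes were lower in mnn++ (7 of 8 below 0, adjusted p = 2.36e-05). Adjusted over the list alone 5 members fell, among them bnk (-0.27 ± 0.06), nullo (-0.28 ± 0.07), halo (-0.29 ± 0.09) and slam (-0.31 ± 0.10). Segmentation genes (15 of 17 below 0, adjusted p = 2.96e-04; hb -0.21 ± 0.07) and dorsoventral genes (8 of 8, adjusted p = 0.0192; twi -0.22 ± 0.08) tested lower and muscle genes higher (9 of 9, adjusted p = 0.0192; Mlc2 0.54 ± 0.28), with 0 members past the threshold. All of these had adjusted p = 0.998 with an estimated correlation. Early zygotic genes were below 0 for 7 of 8 against either control at 2-4 h, with medians of -0.0924 against cntrl1 and -0.323 against cntrl2. The other 3 lists lay near 0 against cntrl1 and rest mostly on cntrl2. Segmentation genes were below 0 for 10 of 17 against cntrl1 (median -0.0055) and 17 of 17 against cntrl2 (-0.178), and dorsoventral genes for 5 of 8 (-0.0215) and 8 of 8 (-0.189). Muscle genes were above 0 for 2 of 9 against cntrl1 (-0.0316) and 9 of 9 against cntrl2 (0.341), with Mlc2 at -0.03 and 1.12. Mnn1 itself was at 0.14 and 0.03 on its spots at 2-4 h and did not pass. A difference in embryo age between the mnn++ and control collections of a window was not tested. At 2-16 h digestive enzymes tested higher (20 of 23 above 0, adjusted p = 1.12e-04; LysE 0.38 ± 0.05, past the threshold adjusted over the list alone), as did cell cycle genes (15 of 21, adjusted p = 0.0459; dup 0.18 ± 0.06). Cuticle genes (10 of 11 below 0, adjusted p = 8.82e-04; Ccp84Ad -0.22 ± 0.07) and muscle genes (8 of 9, adjusted p = 0.00155; bt -0.28 ± 0.12) tested lower there. These 4 lists had adjusted p = 0.749 with an estimated correlation. Their medians at 2-16 h against cntrl1 and cntrl2 were 0.03 and 0.0978 for digestive, 0.0245 and 0.0128 for cell cycle, -0.0432 and -0.139 for cuticle and -0.0305 and -0.34 for muscle genes. At 4-6 and 6-8 h 0 lists passed by camera.

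No single spot passed in a window. The limma counts were 0 at 2-4, 4-6, 6-8 and 2-16 h, with 2226, 3125, 1588 and 814 spots at an unadjusted p under 0.05 against 1519 by chance. The genes of smallest p included CG6012 (0.69), Pink1, a mitochondrial kinase (-0.43), and alpha-Catr (-0.59) at 2-4 h. At 4-6 h they included Ir7g (-0.66), CG3556 (0.53) and Tsp29Fb (0.51). At 6-8 h they included LysE (0.66), thw (-0.80) and the potassium channel gene Shal (-0.46). At 2-16 h, besides Mnn1, they included the cuticle genes TwdlW (-0.68) and TwdlG (-0.50) and Peritrophin-A (-0.53). The F test of a difference between 2-4, 4-6 and 6-8 h called 0 spots (1273 at an unadjusted p under 0.05), with Ir7g and CG6012 at adjusted p = 0.561 and 0.565. Each window rests on 2 controls, and against cntrl2 alone, without the cntrl1 comparison, the counts were 126, 70, 1 and 2, and against cntrl1 alone 0, 10, 11 and 0.

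The controls were compared with each other, since per the labels both carry the driver without the construct. How they differ is not stated. Read through mnn++, 11 spots rose and 1 fell in cntrl1 against cntrl2. The largest differences were on spots 12320 and 12980, which name no single gene. They were chosen after their values were seen, outside the naming rule. By limma they stood at 2.43 ± 0.18 (adjusted p = 6.59e-04) and 2.09 ± 0.14 (adjusted p = 4.33e-04), and the direct arrays gave 2.85 and 2.76. The named genes differed less. CG11164 (0.96 ± 0.12, adjusted p = 0.0338), CG7465 (0.91), CG14683 (0.89 ± 0.07, adjusted p = 6.59e-04), CG7299 (0.83), the lysosomal protease gene cathD (0.65) and CG14889 (0.65) were higher in cntrl1, and CG5568 was lower (-0.81 ± 0.11). The 2 direct arrays at 2-16 h gave 0.72, 0.11, 0.65, 0.24, 0.40, 0.44 and -0.48 for these 7 genes, and all 12 called spots had the same sign there. Digestive enzymes (19 of 23 above 0, adjusted p = 1.25e-04), detoxification genes (14 of 20, adjusted p = 0.0026) and muscle genes (8 of 9, adjusted p = 0.0131) tested higher in cntrl1. Segmentation (16 of 17 below 0, adjusted p = 0.00134) and dorsoventral genes (8 of 8, adjusted p = 0.0117) tested lower. With an estimated correlation these had adjusted p = 0.616, 0.616, 0.781, 0.781 and 0.686. Muscle genes did not hold their direction across windows. Their mnn++ medians against cntrl1 and cntrl2 were -0.0316 and 0.341 at 2-4 h. At 2-16 h they were -0.0305 and -0.34, which puts cntrl1 below cntrl2 there. Among detoxification genes GstD1 (0.46 ± 0.07), GstD4 (0.30 ± 0.07) and GstD3 (0.23 ± 0.05), which are glutathione S-transferases, rose and Cyp4e2 fell (-0.27 ± 0.09), adjusted over the list alone, with 0 members past the threshold over all spots. The count of 12 fell to 3 without 6-8 h, 5 without 4-6 h and 7 without 2-4 h, and rose to 83 without 2-16 h and to 97 with each array as its own value.

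In adults the array carries 1 probe set for Mnn1, and where it lies relative to the null lesions is not known, so it checks nothing about the genotypes. Its mean was 6.04 ± 0.19 (SD, n = 2) in mnn- females and 5.69 ± 0.08 (n = 2) in non-mutant females, and 5.36 ± 0.17 (n = 3) in mnn- males and 5.46 ± 0.08 (n = 2) in non-mutant males. The change of 0.11 ± 0.12 did not pass (adjusted p = 0.884).

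What loss of Mnn1 changed in adults was tested in mnn- against non-mutant flies of both sexes. A pair of probe sets fell and 0 rose: CG9682 by -1.64 ± 0.20 (log2, SE, n = 5 against 4; adjusted p = 0.0377) and CG11911 by -1.10 ± 0.14 (adjusted p = 0.0404). Every mnn- array lay below every non-mutant array of its sex for both. At an unadjusted p under 0.05 there were 1034 probe sets, against 698 by chance. Next in p, and not passed, came the flight muscle genes fln, which encodes flightin (-0.99 ± 0.15, adjusted p = 0.105), and Act88F, an actin (-1.15 ± 0.20, 0.155), the cytochrome P450 gene Cyp6a21 (-0.59 ± 0.09, 0.155), the digestive protease gene Jon99Fi (-2.23 ± 0.38, 0.155), CG18404 (-1.42), CG40485 (-0.42), CG42335 (-0.57) and Idh3b (-0.43). Both calls were lost without either wt array or mnn- female 8, 1 probe set passed without control female 3 or mnn- female 7, and 0 passed when both wt arrays were left out. Over 20 alternatives CG9682 had adjusted p from 0.00401 to 0.156 and CG11911 from 0.00439 to 0.285. With wt and control as separate levels 4 probe sets rose and 22 fell, and with control left out 26 rose and 66 fell, CG9682 and CG11911 among them.

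**Figure D3:**
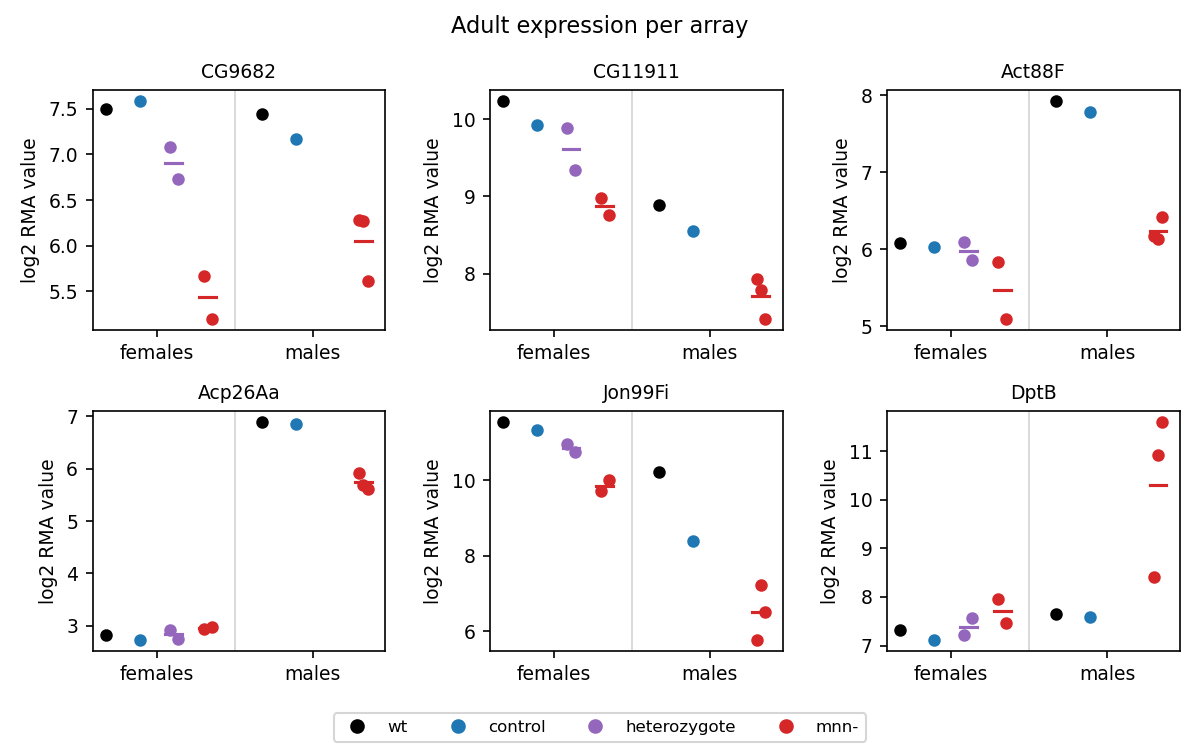
Log2 RMA values of 6 genes on each of the 11 adult arrays, females left and males right of the grey line, coloured by genotype, with bars at the mean where a group has more than 1 array. CG9682 in mnn- flies has means of 5.44 (females) and 6.05 (males) against 7.54 and 7.31 in non-mutant flies, and DptB is high on mnn- male arrays 10 and 11.

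Of the lists, digestive enzymes tested lower in mnn- (23 of 28 below 0, adjusted p = 2.24e-05 by camera, and adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone 4 of them fell, the Jonah proteases Jon99Fi, Jon44E (-1.07 ± 0.21), Jon65Ai (-0.79 ± 0.21) and Jon25Biii (-1.06 ± 0.31), with 0 past the threshold over all probe sets. Muscle genes tested lower too (9 of 10, adjusted p = 0.00755, and adjusted p = 0.665 with an estimated correlation), with the troponin C gene TpnC41C at -0.61 ± 0.16 past the threshold adjusted over the list alone. That difference rests mainly on the control arrays, with medians of 7.755 in the control female against 7.057 in wt and 7.162 and 7.08 in mnn- females, and 9.477 in the control male against 8.893 in wt and 8.454 to 8.775 in mnn- males. With control left out 5 of 10 muscle genes were below 0 (adjusted p = 0.582). Haemocyte and matrix genes were lower (13 of 15, adjusted p = 0.00588), among them the collagen IV genes Col4a1 (-0.38 ± 0.13) and vkg (-0.33 ± 0.13). Detoxification genes (19 of 22, adjusted p = 0.00108; Cyp6g1 -0.48 ± 0.16) and clock genes (7 of 9, adjusted p = 0.0291; tim -0.32 ± 0.17) were lower as well, with 0 members past either threshold. These 3 lists had adjusted p = 0.39 with an estimated correlation. With wt left out detoxification genes had adjusted p = 0.0759 (median -0.0994) and clock genes 0.0742 (median -0.105), so neither list passed there. With control left out haemocyte genes (adjusted p = 0.774), clock genes (0.146) and accessory gland genes (0.188) did not pass. Digestive enzymes and antimicrobial genes passed with either stock left out (6.8e-04 and 0.0283 without wt, 7.69e-05 and 5.93e-04 without control). Antimicrobial genes tested higher (9 of 10 above 0, adjusted p = 2.55e-04, and adjusted p = 0.408 with an estimated correlation), with the peptide genes Mtk at 1.71 ± 0.52 and DptB at 1.69 ± 0.58. This list did not pass within females (6 of 10, adjusted p = 0.814), and its medians were 6.727 and 6.519 in mnn- against 6.488 and 6.495 in non-mutant females, and 7.055, 7.492 and 8.168 in mnn- against 6.668 and 6.875 in non-mutant males. Accessory gland genes were lower (12 of 14, adjusted p = 0.00198, and adjusted p = 0.457 with an estimated correlation).

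The yolk, chorion and vitelline membrane list was lower for all 18 measured members, with a median change of -1.17 (adjusted p = 7.1e-10, and adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone Cp18 fell (-1.75 ± 0.46). The wt arrays stood high for this list, with medians of 11.51 in the female and 8.957 in the male against at most 9.484 and 6.643 on the other arrays of each sex, and without wt the median change was -0.0525. The lists of trithorax and Polycomb genes, DNA damage repair, heat shock proteins and AP-1, JNK and TGF-beta signalling did not pass (adjusted p = 0.884 each), and neither did cell cycle, segmentation and cuticle genes (0.884 each), dorsoventral and sex determination genes (0.911 each), early zygotic and vision genes (0.803 each), neural (0.685), maternal (0.136), fat body (0.129) and testis genes (0.0659). Median, mean and test differed in sign for vision, trithorax and Polycomb, segmentation, AP-1, cuticle, DNA damage, heat shock, cell cycle and dorsoventral genes.

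Within females CG9682 fell (-2.10 ± 0.23, n = 2 against 2, adjusted p = 0.031), and 563 probe sets had an unadjusted p under 0.05. Jon65Ai (-1.29 ± 0.26) and Jon44E (-1.42 ± 0.28) came next and did not pass over all probe sets. Adjusted over the list alone, both fell with Jon99Ci (-1.61 ± 0.36) among digestive enzymes (23 of 28 below 0, adjusted p = 2.12e-06). For that list the wt female stood highest (median 10.24), above 9.455 in the control and 8.792 and 9.262 in mnn- females. On the same terms 5 detoxification genes fell, including GstD1 (-1.49 ± 0.45), Cyp6a23 (-0.89 ± 0.24) and Cyp6w1 (-0.75 ± 0.24), in a list with 19 of 22 below 0 (adjusted p = 5.03e-07) and medians of 6.16 in wt, 5.715 in control and 5.195 and 5.467 in mnn- females. Haemocyte genes (11 of 15 below 0, adjusted p = 0.0154; LanB2 -0.37 ± 0.13) also tested lower, and these 3 lists had adjusted p = 0.482 with an estimated correlation. Yolk and chorion genes were lower for 16 of 18 (adjusted p = 5.03e-07, and adjusted p = 0.607 with an estimated correlation), with medians of 9.264 and 8.965 in mnn- against 9.484 in the control and 11.51 in the wt female. Cell cycle genes were higher for 20 of 21 (adjusted p = 7.64e-05, and adjusted p = 0.73 with an estimated correlation), with Orc1 at 0.42 ± 0.18. The count of 1 became 0 without the wt female, either heterozygote, either mnn- female or mnn- males 9 or 10, and 56 without the control female. Over 16 alternatives CG9682 had adjusted p from 0.00395 to 0.983.

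Within males 4 probe sets fell. They were Acp26Aa, the seminal protein ovulin (-1.13 ± 0.11, n = 3 against 2, adjusted p = 0.00356), Act88F (-1.61 ± 0.18, adjusted p = 0.0135), and, outside the naming rule and chosen after their values were seen, a probe set that names CG43732 and CG42613 (-1.70 ± 0.12, adjusted p = 2.67e-04), and a probe set without a gene name (-0.98 ± 0.13, adjusted p = 0.0452). At an unadjusted p under 0.05 there were 1184 probe sets. Named as well, and not passed, were the seminal protein genes Acp76A (-1.07 ± 0.15, adjusted p = 0.05003) and Acp62F (-0.83 ± 0.14, 0.118), fln (-1.23 ± 0.18, 0.0501), and, higher, CG17349 (0.71 ± 0.10, 0.0501) and the testis kinase gene Tssk (0.76 ± 0.12, 0.108). Acp26Aa passed in 14 of 15 alternatives and Act88F in 16 of 16. Acp26Aa lies on the same chromosome arm as Mnn1, and whether linked variants lowered its signal was not tested. The count was 105 without the control male, 48 without the wt male, 18 without mnn- male 9 and 7 without mnn- male 10.

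Accessory gland genes were lower in mnn- males (12 of 14, adjusted p = 1.57e-07, and adjusted p = 0.592 with an estimated correlation), and adjusted over the list alone 5 fell, among them Acp53C14a (-0.68 ± 0.14). Antimicrobial genes were higher (9 of 10, adjusted p = 7.36e-07, and adjusted p = 0.592 with an estimated correlation). DptB (2.68 ± 0.67), Mtk (2.61 ± 0.61), Def (1.29 ± 0.42) and CecB (0.41 ± 0.14) rose adjusted over the list alone, with DptB at 10.9 and 11.6 in mnn- males 10 and 11 and at 8.41 in male 9. Digestive enzymes (21 of 28 below 0, adjusted p = 0.0181) and muscle genes (9 of 10, adjusted p = 0.0482) tested lower, both with adjusted p = 0.721 with an estimated correlation. For digestive enzymes the control male (median 9.22) lay among the mnn- males (8.983, 9.181 and 9.96) and the wt male above them (10.06), and without the wt male and X113_Y79 arrays the list did not pass (adjusted p = 0.248). The control male stood highest for muscle genes, as above. Testis genes were higher (14 of 20, adjusted p = 0.0131, and adjusted p = 0.597 with an estimated correlation), with tomboy20 at 0.36 ± 0.09. Maternally loaded (16 of 18, adjusted p = 2.30e-04), cell cycle (18 of 21, adjusted p = 0.0149) and yolk and chorion genes (18 of 18, adjusted p = 7.99e-06) were lower, with adjusted p = 0.66, 0.721 and 0.66 with an estimated correlation. The wt male array stood high for all 3, with medians of 5.314 against 4.354 to 4.43 on the other male arrays for maternal, 5.362 against 4.563 to 4.908 for cell cycle and 8.957 against 6.34 to 6.643 for yolk and chorion genes. Without the wt male and X113_Y79 arrays none of the 3 passed (adjusted p = 0.872, 0.186 and 0.882), and cell cycle and yolk genes turned direction.

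Whether the sexes differ in the effect was tested as an interaction. It called 0 probe sets by limma (637 at an unadjusted p under 0.05), with Acp26Aa closest (-1.32, male minus female effect, adjusted p = 0.0619), followed by Acp76A (-1.18), CycT (-0.82) and apt (-0.87) at adjusted p = 0.992. Acp26Aa was low in females of every genotype, with means of 2.77 to 2.96. For Act88F, which fell in males, and CG9682, which fell in females, the interaction was -1.02 ± 0.27 and 0.85 ± 0.32, both with adjusted p = 0.992. The count was 27 without the control male, 10 without the control female, 9 without mnn- male 9 and 2 without the wt male. By camera 7 lists differed, and their values stand in the closing part.

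Heterozygous females, which carry 1 null allele, were compared with non-mutant and with mnn- females. No probe set passed by limma in either: 308 and 641 had an unadjusted p under 0.05. CG9682 was intermediate in heterozygotes, at 6.91 ± 0.24 (SD, n = 2) against 7.54 ± 0.06 in non-mutant and 5.44 ± 0.34 in mnn- females. Its change was -0.63 ± 0.23 against non-mutant (adjusted p = 1.00) and -1.47 ± 0.23 from heterozygote to mnn- (adjusted p = 0.840), so neither step passed. Against non-mutant the count was 40 without the control female and 6 without heterozygote 5, and from heterozygote to mnn- it was 7 without heterozygote 5. The smallest p against non-mutant belonged to CG14110 (0.57 ± 0.11), CG10465 (-0.58 ± 0.14) and the eggshell gene Femcoat (-1.69 ± 0.43). In heterozygotes yolk and chorion genes were lower than in non-mutant females (17 of 18, adjusted p = 1.39e-08), mainly through the wt female, since their medians of 9.453 and 9.004 stood beside 9.484 in the control and 11.51 in the wt female. Lower too were detoxification genes (17 of 22, adjusted p = 0.00283; GstD1 -0.89 ± 0.45). Accessory gland (14 of 14, adjusted p = 5.86e-05; Acp95EF 1.34 ± 0.44) and vision genes (9 of 9, adjusted p = 0.00618; Arr1 0.33 ± 0.28) were higher. All had adjusted p = 0.736 with an estimated correlation. The X113_Y79 female held the male transcripts Mst57Da at 7.26 and Acp95EF at 6.64, against at most 5.13 and 4.66 on the other female arrays.

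From heterozygote to mnn- females digestive enzymes (26 of 28 below 0, adjusted p = 4.17e-06; Jon65Ai -1.09 ± 0.26, past the threshold adjusted over the list alone), muscle (10 of 10, adjusted p = 5.17e-04; Mlc1 -0.59 ± 0.26), haemocyte and matrix (13 of 15, adjusted p = 6.95e-04; vkg -0.55 ± 0.21), vision (8 of 9, adjusted p = 0.00428), detoxification (17 of 22, adjusted p = 0.0216) and accessory gland genes (12 of 14, adjusted p = 0.00428) were lower. Cell cycle genes (21 of 21 above 0, adjusted p = 2.5e-06; dup 0.43 ± 0.22), DNA damage repair (20 of 27, adjusted p = 0.0018; Irbp 0.35 ± 0.13), trithorax and Polycomb (13 of 18, adjusted p = 0.0041; brm 0.40 ± 0.11) and maternal genes (14 of 18, adjusted p = 0.00484) were higher. With an estimated correlation all had adjusted p = 0.461, except maternal genes at 0.526. Without the X113_Y79 and wt male arrays cell cycle (adjusted p = 0.0487), digestive (0.0487) and haemocyte genes (0.0134) passed. The other 7 lists did not: detoxification (0.419), maternal (0.472), trithorax and Polycomb, DNA damage and vision (0.551 each), and muscle and accessory gland genes (0.702 each). For muscle, DNA damage, trithorax and Polycomb, maternal and accessory gland genes the X113_Y79 array carried the difference. There the other heterozygote lay near the mnn- females or beyond them. The medians of the X113_Y79 female, the other heterozygote and the mnn- females were 8.005, 7.151, 7.162 and 7.08 for muscle, 5.851, 6.103, 6.074 and 6.004 for DNA damage, 6.128, 6.259, 6.204 and 6.236 for trithorax and Polycomb, and 7.601, 7.936, 7.955 and 7.945 for maternal genes. For accessory gland genes they were 3.494, 3.2, 3.035 and 3.234 in the same order. By median the heterozygote left after dropping X113_Y79 did not exceed both mnn- females for haemocyte (4.517 against 4.663 and 4.729) or digestive genes (9.181 against 8.792 and 9.262).

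Sex is the other factor of the adult design. With limma 4524 probe sets were higher and 4609 lower in males (5 male and 6 female arrays) of 13966 tested. The 2 heterozygote females had a level of their own, so they add only to the estimate of spread. The highest were the seminal fluid and ejaculatory genes EbpII (7.68 ± 0.35), Acp95EF (7.59 ± 0.30), Mst57Da (7.34 ± 0.31), Ebp (7.34 ± 0.30) and Anp (7.02 ± 0.21), followed by Spn77Bb, Acp63F, lncRNA:CR9284, Spn77Bc, CG12699, Acp26Ab and CG12861 between 5.88 and 6.11. The lowest were nanos (-5.50 ± 0.42) and osk (-5.29 ± 0.42), which pattern the germ line, dhd (-5.20 ± 0.53) and the yolk protein genes Yp1 (-5.14 ± 0.67) and Yp2 (-4.95 ± 0.64), followed by Muc12Ea, Yp3, mtrm, RpS5b, Pxt, smg and CG4570 between -4.93 and -4.30. Their largest adjusted p was 2.65e-05. Of the lists, all 14 accessory gland genes and 19 of 20 testis genes rose, all 21 cell cycle genes, 15 of 18 maternal, 17 of 18 yolk and chorion, 25 of 27 DNA damage repair and 16 of 18 trithorax and Polycomb genes fell over all probe sets. Their camera adjusted p ran from 1.47e-09 to 0.0012, and with an estimated correlation testis genes had adjusted p = 0.074 and the others from 0.281 to 0.543. Muscle (10 of 10 rose), detoxification (18 of 22), fat body (9 of 14) and vision genes (7 of 9) were higher and sex determination genes lower (6 of 10), with adjusted p from 6.9e-04 to 0.0431 and 0.283 to 0.487 with an estimated correlation.

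The non-mutant stocks also differed. In control against wt flies (n = 2 against 2) 32 probe sets rose and 37 fell by limma. The eggshell genes Cp38 (-3.19 ± 0.38, adjusted p = 0.00227), Cp36 (-3.15 ± 0.29, adjusted p = 5.42e-04), Vm34Ca (-3.11 ± 0.47), yellow-g and Cp7Fc fell, with Muc4B (-2.98). CG31676 (1.68 ± 0.17), the lysozyme gene LysP (1.65 ± 0.28), SrpRalpha (1.52 ± 0.13), CG1648 (1.31 ± 0.22) and the odorant-binding protein genes Obp56a (1.36 ± 0.25) and Obp83b rose. Yolk and chorion genes were lower for 18 of 18 (adjusted p = 1.71e-29), with 9 fallen over all probe sets and 17 adjusted over the list alone, and this list also passed with an estimated correlation (adjusted p = 9.25e-04). Muscle genes were higher (10 of 10, adjusted p = 4.34e-08; bt 1.11 ± 0.22), as were haemocyte (9 of 15, adjusted p = 0.00194; Hml 0.58 ± 0.13) and vision genes (9 of 9, adjusted p = 4.54e-04; Arr1 0.70 ± 0.18). Heat shock genes were lower (7 of 11, adjusted p = 0.0180), and the chaperone gene Hsp68 fell over all probe sets (-1.04 ± 0.14). Cell cycle (18 of 21 below 0, adjusted p = 0.00152), maternal (13 of 18, adjusted p = 0.00392) and detoxification genes (16 of 22, adjusted p = 0.0253; Cyp6a2 -1.37 ± 0.21) were lower too. Without the wt male and X113_Y79 arrays cell cycle (adjusted p = 0.382) and maternal genes (0.711) turned direction and haemocyte genes did not pass (0.095). With an estimated correlation the 7 lists other than yolk had adjusted p from 0.107 to 0.658. The count of 69 ran from 25 without the control male to 227 without the wt female, and was 104 without the wt male, 112 without either heterozygote, 45 without mnn- female 8 and 44 without mnn- male 9.

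**Figure D4:**
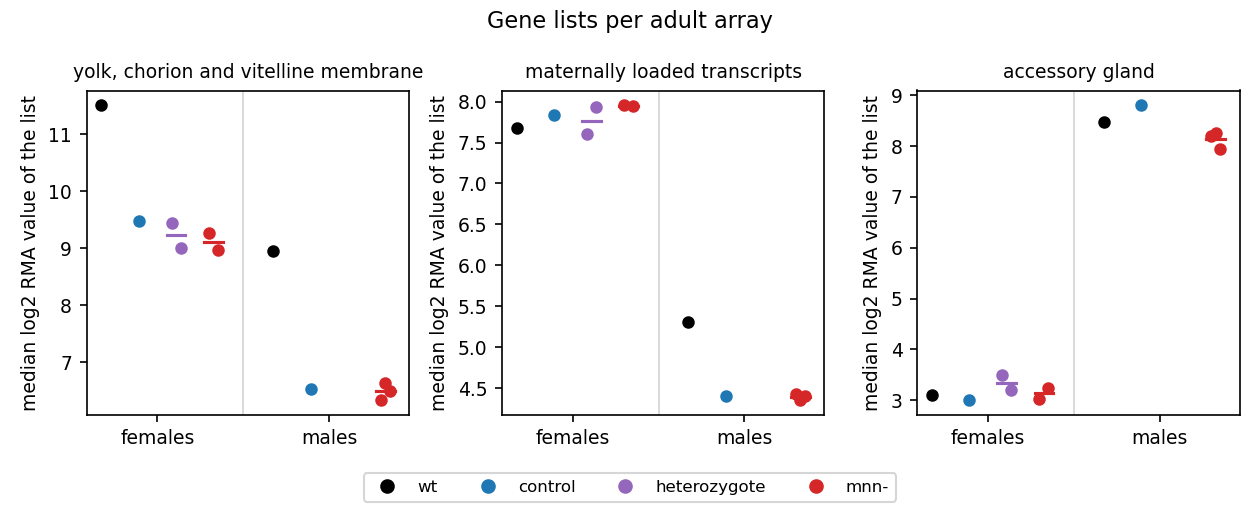
Median log2 RMA value of 3 gene lists on each adult array, females left and males right of the grey line, coloured by genotype, with bars at the mean where a group has more than 1 array. The wt arrays stand highest for yolk and chorion genes (11.51 and 8.957), and the wt male stands above the other males for maternal transcripts (5.314).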

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

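All 5 tests of the 3 patterns weighed here were chosen only after the result was seen, as was the estimate of female signal relative to the wt female array.

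Spots called for mnn++ over 4 windows changed more against cntrl2 than against cntrl1. An effect of mnn++ of one size against both controls was tested at 2-16 h on 145 spots called from the 3 narrow windows alone. In the direction of the call their median there was 0.0125 against cntrl1 (quartiles -0.038 and 0.0725) and 0.168 against cntrl2 (0.0265 and 0.316), and 77.9% of them were larger against cntrl2, which argues against one size for most of these spots. A candidate explanation is that the cntrl2 RNA itself stands apart: of the same 145 spots, 121 (83.4%) had the same sign on the separate arrays of cntrl1 against cntrl2, against 53.9% of all spots. For genes such as CG11164, CG14683 and CG5568 the contrast may therefore show cntrl2 rather than overexpression of Mnn1. What sets cntrl2 apart, a difference in stock, in embryo age or in handling, was not tested, and the labels give none.

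The wt male array held transcripts that are high in females, with Yp1 at 11.6 against 7.3 to 7.6 on the other male arrays. A female sample carrying a male label is argued against by its accessory gland median of 8.477, where females reach at most 3.494 and males at least 7.94. Female RNA mixed into the sample is a candidate explanation: of 73 genes at least 3 log2 units higher in females, this array was the highest male for 70 (95.9%), against 27.7% of all genes and 20% by chance. The signal implied a median of 6.49% female RNA (quartiles 4.99 and 9.03), 6.23% for maternal and 5.16% for cell cycle genes, but 45% for yolk and chorion genes, or 18.8% relative to the wt female array. A single share of mixed RNA therefore leaves part of the yolk and chorion signal open, and no biological explanation was tested.

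Yolk, chorion and vitelline membrane genes were lower in mnn- flies, and the wt arrays stood apart from the others of their sex for this list: 11.51 in the female against 8.965 to 9.484, and 8.957 in the male against 6.34 to 6.643. An effect of losing the second copy of mnn is argued against by a median change of 0.0117 from heterozygote to mnn- females. An effect already complete with 1 copy lost is argued against by the control stock, which has 1 array per sex. With wt left out, also chosen after the result was seen, the median change from control to mnn- flies was -0.0525. Heterozygote medians of 9.453 and 9.004 stood beside 9.484 in the control female. What set the wt arrays apart is left open. A difference in egg production between the stocks or in mating was not tested, and female RNA on the wt male array may add to the male value.

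The rule that picks out a sample far from the others of its sex chose 5 of 74 sets of values. Its cutoffs are meant to pick about 1 in 20 by chance, and that rate was not checked on these data. Besides the yolk and chorion sets the chosen ones included maternally loaded transcripts, with 5.314 on the wt male array against 4.354 to 4.43. Dorsoventral genes had 6.059 on mnn- male 9 against 5.934 to 5.962. Detoxification genes had 7.274 on mnn- male 11, the only Y79_Y79 array, against 6.811 to 6.942.

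In 7 lists the effect of mnn- differed between males and females by the interaction test. The male effect was lower than the female one for accessory gland (adjusted p = 9.63e-07, 12 of 14 members), cell cycle (1.14e-06, 20 of 21), maternally loaded (1.98e-05, 15 of 18), DNA damage repair (0.0183, 19 of 27) and trithorax and Polycomb genes (0.0184, 13 of 18). It was higher for antimicrobial (8.87e-05, 10 of 10) and detoxification genes (0.00255, 17 of 22). Accessory gland genes had medians of at most 3.494 in females and at least 7.94 in males, so a fall in females could hardly have shown. For this list the test largely repeats the result in males. With an estimated correlation the adjusted p was 0.638 for DNA damage repair and 0.539 for the other 6. Without the wt male and X113_Y79 arrays it was 1.72e-10 for accessory gland, 0.0132 for antimicrobial and detoxification, 0.0302 for trithorax and Polycomb, 0.109 for cell cycle and maternal and 0.253 for DNA damage repair genes.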

How the results depend on the processing

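The alternatives chosen only after the data were seen are the difference from both controls, leaving out the wt male and X113_Y79 arrays, pairing males with females of the same stock or allele pair, control left out, and lists with wt or control left out. The array numbers run on across groups, so none pairs arrays. Under settings other than leaving out a replicate, the named genes kept direction and side of the threshold 753 times, and kept direction alone 31 times with a call gained and 90 times with a call lost. Leaving out a replicate gave 1223, 24 and 107. Only spots with a value on every array were tested in the first place, so that filter is no separate check and is not counted. The causes of the changes below were not tested.

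For mnn++ over 4 windows the count of 79 became 0 with each array as its own value, 0 against cntrl1 alone, where CG14683 (-0.0734) and CG5568 (0.000125) reversed, and 0 against both controls. It split into 84 higher and 15 lower with arrays centred and scaled. Leaving out a window gave 2 to 145, and for cntrl1 against cntrl2 3 to 83, with 97 for each array as its own value. In single windows 6-8 h gave 2 with equal median absolute deviation and 8 with each array as its own value, 2-16 h gave 3 in that way, and 2-4 h gave 1 with robust eBayes. Leaving out a control gave 0 to 126 at 2-4 h, 10 to 70 at 4-6 h, 1 to 11 at 6-8 h and 0 to 2 at 2-16 h.

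For mnn- against non-mutant adults the count of 2 became 0 with trend and robust eBayes, 0 under quantile normalization, 0 with wt left out, 92 with control left out, 26 with wt and control as separate levels and 1 without the wt male and X113_Y79 arrays. Females gave 0 under quantile normalization, 2 from female arrays only and 0 without those 2 arrays. Males gave 1 with probe sets above the median, 7 with trend and robust eBayes, 2 from male arrays only and 54 without those 2 arrays. The interaction gave 2 with trend and robust eBayes, 1 without those arrays and 1 with the sexes paired over 4 pairs, where Acp26Aa had adjusted p = 0.217 (0.0104 to 0.663 over its alternatives), control against wt gave 133 without them, and male against female gave 5344 with probe sets above the median and 8702 with the sexes paired. Leaving out each array gave 0 to 3 for mnn- against non-mutant, 0 to 56 in females, 3 to 105 in males, 0 to 40 for heterozygotes, 0 to 7 for mnn- against heterozygotes, 0 to 27 for the interaction, 8548 to 9160 for sex and 25 to 227 for control against wt. Where a group was left with 1 array, it was assumed to vary like the others. The adult Mnn1 probe set, not past the threshold, changed sign on leaving out arrays: in control against wt it ran from -0.234 to 0.236 (-0.0812 without the control male), in heterozygotes from -0.0592 to 0.27 and in males from -0.166 to 0.0017.

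With camera and an estimated correlation 0 lists passed for mnn++ over 4 windows, 2-4 h, 2-16 h, cntrl1 against cntrl2, mnn- against non-mutant adults, females, males, heterozygotes, mnn- against heterozygotes, the interaction and sex, and 1 for control against wt. For sex the accessory gland list was missed although its medians were at most 3.494 in females and at least 7.94 in males. A list missed in this setting is therefore not shown to be unchanged. Without the wt male and X113_Y79 arrays 11 lists passed in females, 3 for mnn- against heterozygotes and 5 for control against wt. For mnn- against non-mutant adults 7 lists passed with wt left out and 5 with control left out, where muscle genes turned direction (adjusted p = 0.582). Without the wt male and X113_Y79 arrays the direction turned for cell cycle (adjusted p = 0.186) and yolk genes (0.882) in males and for cell cycle (0.382) and maternal genes (0.711) in control against wt. Signal over background of the embryo arrays was not analysed here. In adults a low level, as of Acp26Aa in females, leaves no room for a fall.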

Other observations

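The tests of chromosome arms, of the neighbours of Mnn1, of gain against loss and of other splits were planned before their results were seen, but the reading of the first 2 was changed after it: a missed threshold is not taken to exclude the explanation. The look at the X113_Y79 array and the lists with wt or control left out were chosen only after the result was seen.

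Whether genes called for mnn++ or between the controls gather on a chromosome arm, as linked background between stocks could give, was tested on 42 such genes. The smallest adjusted p over arms by Fisher's exact test was 0.838. Arm 2R held 26.2% of the called genes against 20.1% of those tested, and the upper bound of its odds ratio was 2.89, so a moderate excess is not excluded. A test by whole arm cannot see grouping within an arm. Among the called genes cn and cathD lie close together on 2R, and CG14683 and tomboy20 on 3R. Whether called genes group locally more than others was not tested.

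Genes within 1 Mb of Mnn1 may differ in mnn- flies through linked variants. Of 232 probe sets there, 24 (10.3%) had an unadjusted p under 0.05 in mnn- against non-mutant adults, against 7.46% elsewhere (one-sided Fisher's exact p = 0.0682). The threshold was missed, which leaves linkage open. Acp26Aa, called in males, lies on the same arm just beyond this distance. It was therefore not counted among the neighbours, and linkage is open for it too.

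If gain in embryos and loss in adults acted oppositely on the same genes, their changes would be inversely related. Across 10186 genes, which are not independent, Spearman's rho was -0.0328 and Pearson's r -0.028, short of the rho of -0.1 set beforehand. Noise lowers such values, and the stages differ, so opposite effects on a smaller set of genes were not tested.

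For mnn++ over 4 windows the real signs of the windows called 79 spots, and the highest of the other sign choices 0. For cntrl1 against cntrl2 these were 12 and 0. In each, 1 choice of 8, the real one, called as many, and 8 are too few for a share under 0.05. For mnn- against non-mutant adults 1 of 60 splits within the sexes, the real one, called as many as 2 probe sets, and the highest other called 1. That margin is small. Males and females of a stock or allele pair were also split freely, and the real split separates the stocks as well. Chance is therefore not excluded there. For male against female 1 of 100 drawn splits, the real one, called 9133, and the highest other 6650, so chance can be excluded there. Which arrays made up the split with 6650 calls was not examined.

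The X113_Y79 heterozygote female was the highest of the females for 72 of 140 genes at least 3 log2 units higher in males (51.4%, against 16.7% by chance). Its accessory gland median was 3.494.

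With wt left out, 7 lists passed for mnn- against control, which leaves 2 control arrays as the reference. Muscle genes, for which those arrays stand high (7.755 and 9.477, against 7.057 and 8.893 on wt arrays), had a median change of -0.54 (adjusted p = 4.65e-08), haemocyte and matrix genes -0.23 (1.25e-05), digestive enzymes -0.201 (6.8e-04), accessory gland genes -0.343 (9.08e-04), vision genes -0.183 (0.0149), antimicrobial genes 0.427 (0.0283) and cell cycle genes 0.122 (0.00216). With an estimated correlation haemocyte genes had adjusted p = 0.0792 and the other 6 from 0.507 to 0.593. Of the 8 lists that passed with wt, 5 passed here in the same direction. Those lost were yolk and chorion (adjusted p = 0.781), detoxification (0.0759) and clock genes (0.0742). With control left out, 5 lists passed for mnn- against wt: yolk and chorion (1.85e-37), detoxification (7.33e-05), digestive (7.69e-05) and maternal genes (0.00346) lower and antimicrobial genes (5.93e-04) higher. With an estimated correlation yolk genes had adjusted p = 0.00123 there and the other 4 from 0.692 to 0.807. Muscle genes had a median change of -0.00147 there (0.582).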
